A study of Mus musculus with 36 samples.

How the data were processed

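Gene-level read counts of 36 RNA sequencing libraries were analysed, 3 for each of 12 groups formed by 3 ages and 4 sorted blood progenitor populations. Each library was assigned to its group and replicate from its title in the labels. The labels call the libraries of a group biological replicates and give each age as pooled male and female C57Bl/6 wild-type mice. The labels do not say whether a replicate is 1 animal or a separate pool, and the adjusted p-values measure the spread between these libraries. The main fit and the list tests count the 36 libraries as independent.

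Per the labels' protocols, cells were sorted on several days, RNA was taken from at least 5000 cells per sample, and all libraries were prepared together with a low-input kit and sequenced as 50-base read pairs with a target of 40 M reads (1 M = 1e6). Per the submitters' processing notes, the tools were FastQC, MultiQC, STAR and featureCounts with the mouse build GRCm38; their versions, the annotation and the strand setting of the counting are not given in the sources used here. The deposited values are whole-number counts per gene, 1 file per library, for 52459 gene symbols, and the authors had not normalized them. No entry lacked a gene name. Of these symbols, 48108 were found in GENCODE M21, an annotation of GRCm38, and they held 99.39% of the counts. Gene identifiers and coordinates come from that annotation, and 101 symbols shared by more than one gene were left without coordinates. Without a stated strand setting, the reads of overlapping and antisense genes cannot be told apart, and near-identical paralogs such as H2-Q6 and H2-Q7 or the globin genes may share or lose reads.

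The libraries held 32.0 to 51.3 M counts (median 40.2), with 13911 to 15788 genes at 10 counts or more in each. Mitochondrial mRNA took 0.25% to 0.86% of the counts, and the 10 most abundant genes 2.44% to 4.34%. Each of the 36 pairs of replicates differed by far more than counting noise, with a chi-square of 16.48 to 264.17 per degree of freedom, so no library was counted as a copy of another.

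Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test (glmQLFit and glmQLFTest). The model held the 12 group means of all 36 libraries, TMM scaling factors (0.899 to 1.113) and the genes kept by filterByExpr with a minimum count of 10, which left 17987 genes. The biological coefficient of variation was 23.2%, and the prior degrees of freedom were 5.36. Contrasts were the difference between 2 ages averaged over the 4 populations or within each population, the difference of each multipotent progenitor from HSC averaged over the 3 ages, and tests of whether an effect differed between populations or between ages. A gene was called at a Benjamini-Hochberg adjusted p under 0.05; for a difference between effects, the highest and lowest effect also had to be at least 1 log2 unit apart. Levels are given as counts per 1e6 (CPM), computed from the deposited counts with the TMM factors, as mean ± SD of 3 libraries. Changes are log2 differences ± SE, where the SE is the size of the difference divided by the square root of the F statistic of its test. Fitted log2 values of genes near 0 in a group, and so their SE, depend on the prior count, so levels are given for those genes.

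Gene lists, contrasts, the test, the rule for naming genes and most alternatives were fixed before the data were examined. The lists hold 37 sets of genes for lineages, other cell types, RNA quality, inflammation, antigen presentation, metabolism and growth, and 35 of them were tested in the 6 averaged contrasts, 210 tests in all. The test was camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 210 tests. Of 101 list calls, 32 also passed with a correlation estimated from the data. Where a call did not, its adjusted p with an estimated correlation follows it. The fry test, which asks whether a list's genes move on balance in one direction and does not compare them with other genes, was run as an alternative. Beside the number of members called over all genes stands the number called when p-values were adjusted over the list alone.

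The genes named are the 6 largest increases and decreases of each averaged contrast among called genes of known name with a level of at least 10 CPM and the same direction in each population or age, the 2 members of each described list with the smallest p-values, a fixed panel of sort-gate, lineage, fetal, interleukin-10 receptor and interferon genes, and the 6 genes with the smallest p-values in each test of age effects between populations. Some genes that this rule selects are not reported here. Other genes were chosen after their values were seen, and are named where a list held 5 or fewer exceptions to its direction or where a library stood apart.

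The calculations were tested on simulated negative binomial counts that shared each gene's mean over the 36 libraries, its dispersion and the library sizes, with known changes put in; 17395 genes were tested. For E18.5 minus adult averaged over the populations, 74.6% of the genes changed 1.5-fold were recovered, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold, with a false share of 4.6% of calls. For E18.5 minus adult within MPP4 the recovered shares were 22.4%, 70.1% and 92.4%. With nothing changed, 2 weeks minus adult gave 0 calls. Of genes raised 4-fold in E18.5 HSC alone, 84.5% were recovered as differing between populations, with a false share of 6.6%. A simulated list of raised genes was called, and 0 of 34 unchanged lists were. Genes and libraries were drawn independently, so lists of correlated genes and effects shared between libraries were not tested.

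The alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other expression filters, a stricter threshold, fits with the compared libraries only, replicate blocks and the omission of each library in turn. After the data were seen, fits without the 3 libraries with the most mRNA of the liver gene Alb or the mast cell gene Tpsb2, without the 4 E18.5 libraries numbered 2, and with a correction for exon length and GC content were added. Scaling alternatives moved the median log2 difference of all genes by at most 0.071 in size. Each of the 24 counts of genes was also compared with other divisions of the same libraries into groups of the same sizes. For averaged contrasts and their differences 30 divisions were counted, the real one included, a number set by run time; 3 against 3 libraries give 10.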

Results

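RNA was sequenced from 4 populations of blood-forming cells sorted from mice of 3 ages, fetal liver at embryonic day 18.5 (E18.5), bone marrow at 2 weeks and bone marrow of adults of 8 to 12 weeks. The populations are stem cells (HSC: Flk2−, CD150+, CD48−) and the multipotent progenitors MPP2 (Flk2−, CD150+, CD48+), MPP3 (Flk2−, CD150−, CD48+) and MPP4 (Flk2+, CD150−, CD48+), each lineage-negative, cKit+ and Sca1+. The mice were unchallenged C57Bl/6 wild types, and each of the 12 groups has 3 libraries, described in the labels as biological replicates from pooled males and females. Each library held 32.0 to 51.3 M counts (1 M = 1e6): 32.0 to 45.1 M at E18.5, 35.5 to 41.3 M at 2 weeks and 33.4 to 51.3 M in adults. The comparisons between ages ask which genes differ between fetal, young and adult cells of the same sort gate, and the comparisons with HSC ask which programs set each progenitor apart. Tests between them ask which age differences depend on the population. Fetal cells come from liver and the others from marrow, so age and tissue cannot be separated where E18.5 is compared.

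Libraries were ordered first by population and then by age. The first principal component held 24.2% of the variance and ran from HSC (−91.0 to −80.0) over MPP2 (−28.7 to −2.6) to MPP3 (12.0 to 59.1) and MPP4 (35.0 to 74.2). On the second, with 13.3%, the E18.5 libraries lay at 21 to 68.3, those of 2 weeks at −29.0 to 29.6 and those of adults at −84.7 to −21.2. Replicates of a group correlated at 0.961 to 0.994.

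**Figure D1:**
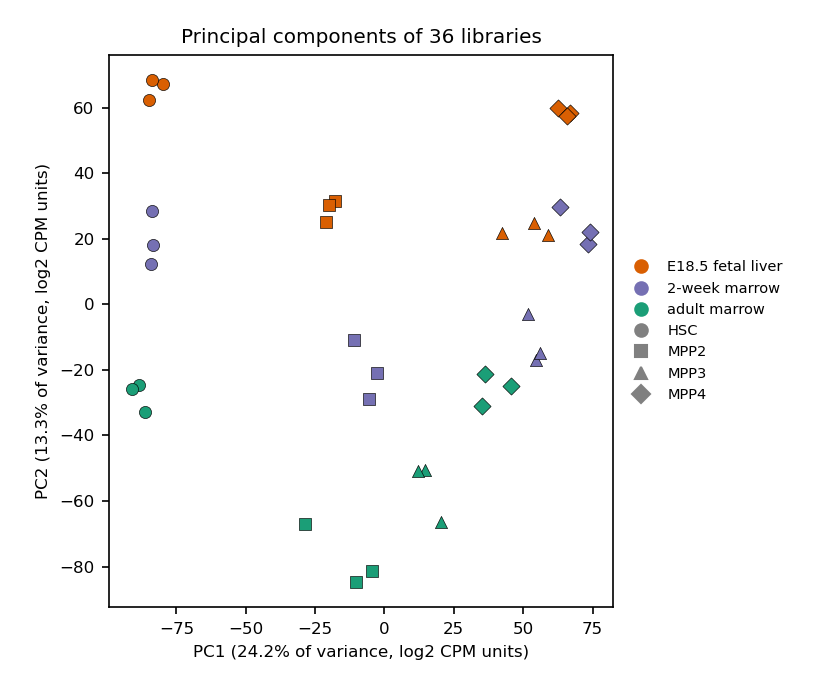
Each point is 1 library placed by its scores on the first (24.2% of variance) and second (13.3%) principal components of log2 CPM, colored by age and shaped by population. HSC lie at −91.0 to −80.0 on the horizontal axis, and E18.5 libraries at 21 to 68.3 on the vertical axis.

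Fetal cells carried mRNA for RNA-binding proteins of the Lin28b axis, an axis known to hold blood progenitors in a fetal state. Igf2bp3, a reader of fetal mRNAs (ENSMUSG00000029814.10, GRCm38 chromosome 6, 49085223 to 49214957), stood at 58.1 ± 6.7 CPM in E18.5 HSC and 186 ± 0.65 in E18.5 MPP4, against 0.696 ± 0.28 and 1.30 ± 0.81 in adults (mean ± SD, n = 3 each). Averaged over the 4 populations it was 7.13 ± 0.17 log2 units higher at E18.5 than in adults (12 libraries per age, counted as independent, adjusted p = 7.0e-24). Its relative Igf2bp1 (chromosome 11, 95957163 to 96005940) had 17.4 to 41.2 CPM at E18.5 and under 0.3 CPM in each group of the other ages, a difference from adults of 8.31 ± 0.31. Lin28b itself (chromosome 10, 45376620 to 45486395) was 6.29 ± 0.40 higher (7.5e-14) and the chromatin protein Hmga2 3.25 ± 0.09 higher (5.3e-22). The differentiation inhibitor Dlk1 (chromosome 12, 109452823 to 109463336) was 5.64 ± 0.18 higher, the imprinted noncoding RNA H19 5.05 ± 0.50, and the transcription inhibitor Id3 5.23 ± 0.26.

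Of 17987 genes tested, 6701 differed between E18.5 and adult cells, 3286 higher and 3415 lower at E18.5, and 2051 of them more than 2-fold (956 higher, 1095 lower). The direction was the same in each of the 4 populations for 80.8% of these genes. Without the 3 libraries with the most Alb or Tpsb2 mRNA 6168 genes differed, without the 4 E18.5 libraries numbered 2 the count was 6538, and with a correction for exon length and GC content 7666. The last count had more genes higher (4037) than lower (3629). With limma-voom and a random block by the number in the deposited names the count was 4325, although the labels do not pair libraries by it. Within single populations 2128 genes differed in HSC, 2272 in MPP2, 3412 in MPP3 and 2763 in MPP4; from the compared libraries alone the counts fell to 1024 in MPP2 and 1027 in MPP3.

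**Figure D2:**
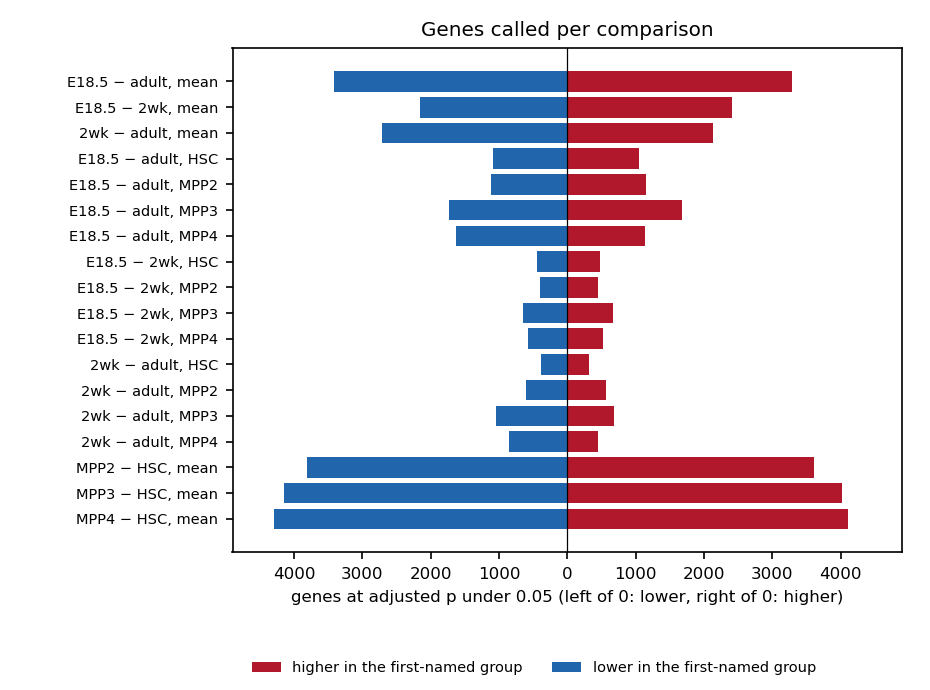
Bars give the number of genes at adjusted p under 0.05 for each comparison, lower in the first-named group to the left and higher to the right. The E18.5 minus adult mean has 3415 and 3286 genes, and MPP4 minus HSC has 4294 and 4101.

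Of the 10 measured genes of the Lin28b list 9 were higher at E18.5 than in adults, 0 lower and 1 not past the threshold (9 higher adjusted over the list alone), with a median difference of 2.58 (list adjusted p = 2.3e-15). Of 18 imprinted genes, mostly regulators of growth, 12 were higher and 0 lower (12 and 1 adjusted over the list alone), with a median of 1.79 (1.2e-08). They include the cell cycle brakes Ndn (1.92 ± 0.11) and Cdkn1c (1.61 ± 0.10). Of 31 proliferation genes 17 were higher and 0 lower (19 and 0 adjusted over the list alone), by a median of 0.26 (2.8e-05; adjusted p = 0.18 with an estimated correlation). Of 54 replication-dependent histone genes, set as a sign of RNA quality, 16 were higher and 3 lower (16 and 2 adjusted over the list alone), with a median of 0.37 (0.0058, and adjusted p = 0.63 with an estimated correlation). The median was 0.11 without the E18.5 libraries numbered 2.

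Antigen presentation genes were lower in fetal cells. All 16 measured MHC class I genes were lower at E18.5 than in adults (16 adjusted over the list alone), with a median of −1.17 (4.4e-20). The largest differences were in the nonclassical genes H2-Q6 (−7.78 ± 0.16; ENSMUSG00000073409.12, chromosome 17, 35424850 to 35430055) and H2-Q7 (−7.57 ± 0.15; ENSMUSG00000060550.16, 35439155 to 35443773), close paralogs between which reads may be shared. H2-Q7 stood at 5.53 ± 1.5 CPM in E18.5 HSC and 0.796 ± 0.15 in E18.5 MPP4, against 343 ± 58 and 286 ± 66 in adults. Of 10 MHC class II genes 9 were lower and 1, H2-DMb2, higher (9 and 1 adjusted over the list alone), with a median of −2.28 (1.1e-11). The class II chain H2-Aa fell by 5.05 ± 0.26, H2-Ab1 by 2.56 ± 0.12 and the invariant chain Cd74 by 3.57 ± 0.27 (4.9e-12). Macrophage markers were lower as well (list median −2.01), and in adult MPP2 Cd74 stood at 36.2, 50.4 and 12.9 CPM in the 3 libraries where the macrophage gene C1qa had 28.7, 46.5 and 8.13. In adult HSC Cd74 was 166, 137 and 76.4 CPM beside C1qa at 8.03, 7.41 and 3.18. In adult MPP4 it was 86.9, 60.8 and 42.5 beside 3.86, 3.24 and 2.55, and in adult MPP3 21.9, 30.4 and 10 beside 9.29, 4 and 3.37. Between adult populations Cd74 thus did not follow C1qa.

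Interferon response genes went the other way. Of 36 genes 25 were higher at E18.5 than in adults and 1, Zbp1, lower (26 and 1 adjusted over the list alone), with a median of 0.75 (8.2e-14). The ubiquitin-like modifier Isg15 was 1.91 ± 0.09 higher (62.6 ± 2.0 against 13.1 ± 2.0 CPM in HSC), the interferon-induced receptor chaperone Rtp4 1.66 ± 0.07, and Irf7, a transcription factor of interferon genes, 1.84 ± 0.11 (1.5e-14), by 1.56 to 2.07 in each population.

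Of 24 NF-kB target genes 13 were lower at E18.5 than in adults and 1, the chemokine Ccl4, higher (14 and 1 adjusted over the list alone), with a median of −0.49 (2.2e-04; adjusted p = 0.19 with an estimated correlation). Nfkbia, the feedback inhibitor, fell by 0.88. Of 20 immediate early and dissociation genes, set as a sign of cell handling, 11 were lower and 2, Jund and Nr4a1, higher (11 and 2 adjusted over the list alone), with a median of −0.39 (0.0033; adjusted p = 0.44 with an estimated correlation); Jun fell by 1.86 ± 0.23. A further list held 26 measured genes of Toll-like receptors, other innate sensors and their signalling proteins. Of these 9 were lower and 3, the Toll-like receptors Tlr5, Tlr2 and Tlr7, higher (9 and 3 adjusted over the list alone; 0.023; adjusted p = 0.068 with an estimated correlation).

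Of 17 megakaryocyte genes 9 were lower at E18.5 than in adults and 2 higher (9 and 3 adjusted over the list alone), with a median of −0.76 (0.0031; adjusted p = 0.14 with an estimated correlation). The platelet integrin Itga2b fell by 1.91 ± 0.13 and the platelet chemokine Pf4 by 2.04 ± 0.22, from 132 ± 94 CPM in adult HSC to 11.8 ± 4.8 in E18.5 HSC. Of 21 granulocyte-monocyte genes 7 were higher and 10 lower (7 and 10 adjusted over the list alone), and the list did not pass (0.86). Among the higher ones were the granule enzyme Mpo (1.26 ± 0.16, 3.2e-07) and the growth factor receptor chain Csf2rb (1.33 ± 0.11). Of 16 lymphoid genes 5 were higher and 3 lower (5 and 3 adjusted over the list alone; list 0.86). Of 21 HSC signature genes 7 were higher and 7 lower (8 and 8 adjusted over the list alone), and the stem cell genes Procr (−0.26, 0.073) and Mecom (−0.24, 0.14) did not pass. Of the 5 genes of the sort gates, Cd48 (0.94 ± 0.13) and Flt3 (0.52) were higher and Ly6a lower (−0.41), and Kit (−0.31, 0.051) and Slamf1 (0.33, 0.084) did not pass, but did with DESeq2 (0.042 and 0.026).

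Among metabolic lists, glycolysis had 13 of 18 genes higher and 2 (Hk1, Aldoc) lower (13 and 3 adjusted over the list alone), with a median of 0.68 (4.9e-08; adjusted p = 0.18 with an estimated correlation). The glycolytic mutase Pgam1 was 0.94 higher and the lactate carrier Slc16a3 1.91. Of 80 oxidative phosphorylation genes 35 were higher and 1 (Atp5s) lower (35 and 1 adjusted over the list alone), with a median of 0.21 (2.9e-06; adjusted p = 0.65 with an estimated correlation), which was 0.01 without the E18.5 libraries numbered 2. The DNA methyltransferases Dnmt3b (1.61 ± 0.10) and Dnmt3a (1.04 ± 0.11) were higher, within a Polycomb and DNA methylation list that did not pass (4 of 18 higher, 3 lower; the same adjusted over the list alone; 0.44).

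Markers of other cells varied beside these differences. Of 14 macrophage genes 10 were lower at E18.5 than in adults and 1 (Clec4f) higher (10 and 1 adjusted over the list alone), with a median of −2.01 (4.3e-05; adjusted p = 0.21 with an estimated correlation), or −3.04 without the 3 libraries with the most Alb or Tpsb2. The hemoglobin scavenger receptor Cd163 fell by 5.01 ± 0.19. The summed macrophage list stood at 26.1 to 49.0 CPM in the E18.5 groups and 70.1 to 288 in the adult groups, highest in adult MPP2. Of 12 neutrophil genes 7 were lower and 2 (Cxcr2, Ltf) higher (7 and 2 adjusted over the list alone), with a median of −3.30 (0.0043; adjusted p = 0.15 with an estimated correlation). Hepatocyte genes had 5 of 14 lower and 0 higher (5 adjusted over the list alone; list 0.42), and their median of −1.31 turned to 1.38 without these 3 libraries. In adult MPP2 replicate 3, Alb stood at 211 CPM and Afp at 260, in adult MPP3 replicate 3 Alb at 10.8, and in E18.5 MPP3 replicate 1 the mast cell protease Tpsb2 reached 6020 CPM; these 3 libraries were chosen after their values were seen, and others hold less of such mRNA.

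**Figure D3:**
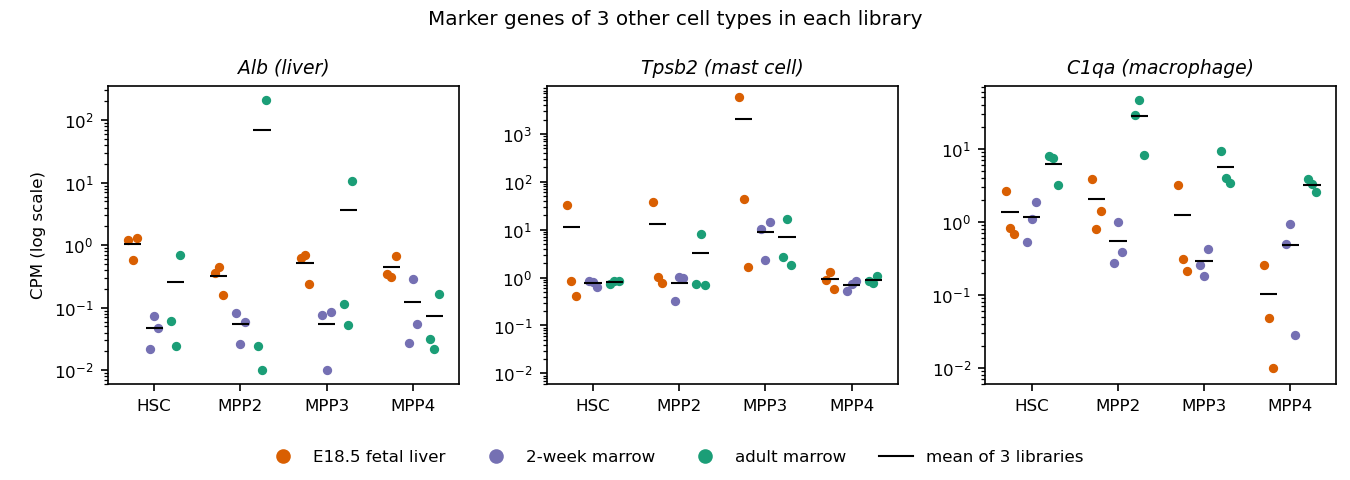
Each point is the CPM (log scale) of a liver, mast cell or macrophage gene in 1 library, by population and age, with lines at the mean of 3 libraries and values under 0.01 CPM drawn at 0.01. Alb reaches 211 CPM in adult MPP2 replicate 3 and Tpsb2 6020 CPM in E18.5 MPP3 replicate 1.

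Compared with marrow at 2 weeks, E18.5 cells differed in 4566 genes, 2414 higher and 2152 lower, with the same direction in each population for 88.9%. More than 2-fold differences were found in 1218 (627 higher, 591 lower). The largest increases again included Igf2bp1 (8.19 ± 0.31, 1.8e-18), Dlk1 (4.70 ± 0.17) and Id3 (4.59), joined by the secreted matrix protein Nov (3.92 ± 0.31). The lymphoid polymerase Dntt (−3.64 ± 0.18, 7.0e-16), Cd163 (−3.88 ± 0.18) and H2-Q7 (−3.03 ± 0.13) were lower. Without the 3 libraries with the most Alb or Tpsb2 4713 genes differed, without the E18.5 libraries numbered 2 the count was 4986, and with the length and GC correction 5693. At an adjusted p under 0.01 it was 2986. With limma-voom and a random block by the number in the titles it was 2974, and by the number in the deposited names 2110. Of the Lin28b list 8 of 10 genes were higher and 0 lower (8 adjusted over the list alone), with a median of 1.17 (1.6e-11). The step was unequal between its genes: Lin28b was 2.15 ± 0.30 higher (2.7e-06), but Igf2bp3 0.82 ± 0.13 (1.2e-05), still at 31.3 ± 7.5 CPM in HSC and 118 ± 17 in MPP4 at 2 weeks. Of 18 imprinted genes 14 were higher and 1 (Sgce) lower (14 and 1 adjusted over the list alone; median 1.74, 3.9e-09).

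Of the 3 age comparisons, this one had the largest median difference of interferon genes. Of 36 genes 34 were higher at E18.5 than at 2 weeks and 0 lower (35 adjusted over the list alone), with a median of 1.25 (3.2e-40), among them Isg15 (2.33 ± 0.09), Rtp4 (2.02 ± 0.07) and Irf7 (1.97 ± 0.11, 1.2e-14). Irf7 (chromosome 7, 141262706 to 141266481) stood at 95.7 to 190 CPM in the E18.5 groups and 19.1 to 54.8 at 2 weeks. MHC class I genes were lower, 13 of 16 with 0 higher (15 adjusted over the list alone), with a median of −0.56 (4.9e-15), and so were 9 of 10 class II genes (9 adjusted over the list alone; −0.88, 1.6e-09). The classical class I chain H2-K1 fell by 1.17 ± 0.05 (2.7e-16).

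Glycolysis had 15 of 18 genes higher at E18.5 than at 2 weeks and 0 lower (15 adjusted over the list alone), with a median of 0.53 (1.7e-11; adjusted p = 0.079 with an estimated correlation), including the glucose carrier Slc2a1 (1.28). Cholesterol synthesis had 12 of 17 higher and 0 lower (13 adjusted over the list alone), with a median of 0.38 (5.2e-06; adjusted p = 0.22 with an estimated correlation). Of 20 immediate early and dissociation genes 10 were lower and 1 (Hspa1b) higher (11 and 2 adjusted over the list alone), with a median of −0.59 (6.4e-05; adjusted p = 0.26 with an estimated correlation). Granulocyte-monocyte genes had 9 of 21 higher and 2 (Srgn, Csf2ra) lower (9 and 2 adjusted over the list alone), with a median of 0.32 (0.0069; adjusted p = 0.42 with an estimated correlation). Histone genes had 6 of 54 higher and 16 lower (7 and 18 adjusted over the list alone), with a median of −0.36 (0.0017, and adjusted p = 0.57 with an estimated correlation), or −0.64 without the E18.5 libraries numbered 2. T and NK cell genes had 0 of 11 higher and 3 lower (1 and 3 adjusted over the list alone), with a median of −0.34 (0.023, and adjusted p = 0.24 with an estimated correlation). Macrophage genes had 4 of 14 higher and 2 lower (4 and 2 adjusted over the list alone), and the list did not pass (0.56). Csf1r, the receptor for macrophage growth factor, rose by 1.88 ± 0.18 and Mpo by 0.98 ± 0.16. The mast cell protease Tpsb2, 4.05 ± 0.92 higher, had 2.43 without E18.5 MPP3 replicate 1 and was not called by limma-voom (0.52).

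**Figure D4:**
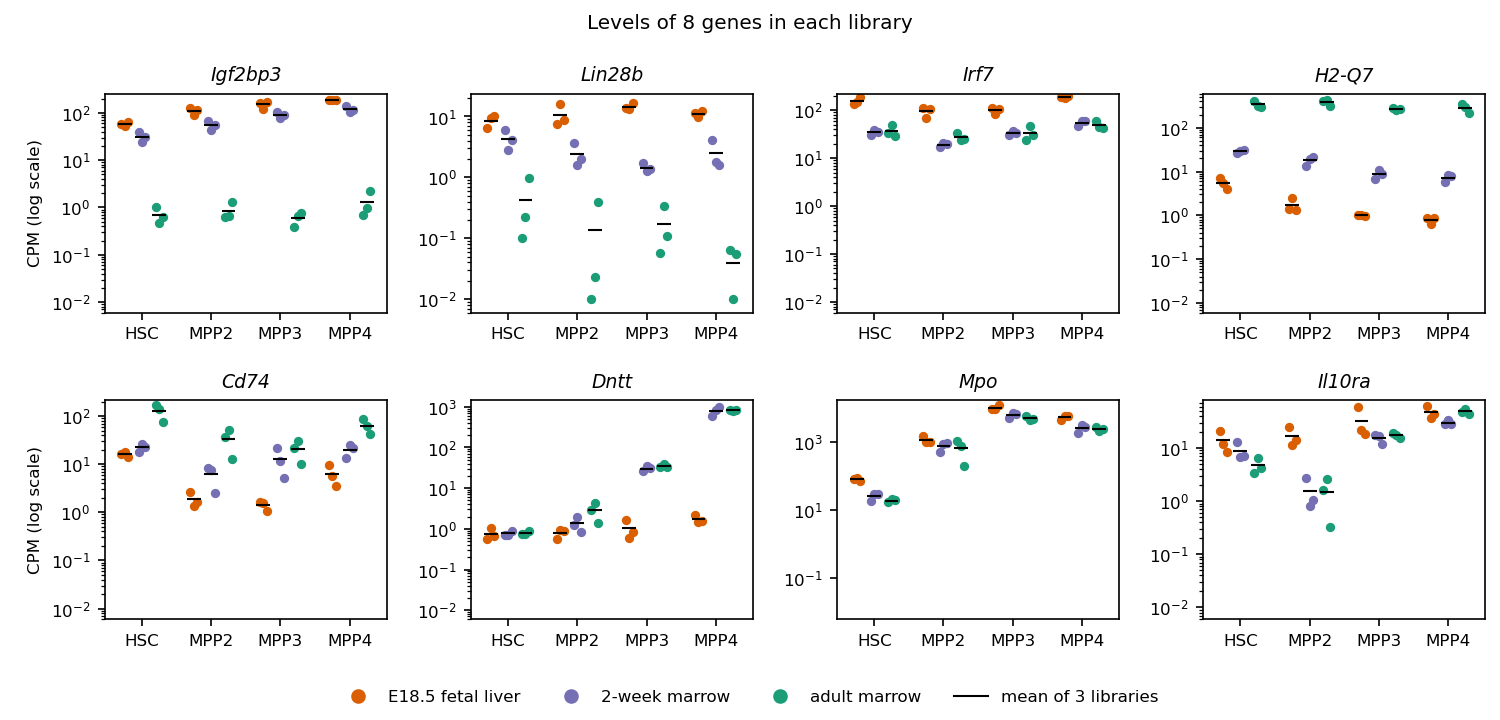
Each point is the CPM (log scale) of a gene in 1 library, by population and age, with lines at the mean of 3 libraries and values under 0.01 CPM drawn at 0.01. Igf2bp3 stays at 31.3 to 118 CPM at 2 weeks and is near 1 CPM in adults, and Dntt in MPP4 goes from 1.77 CPM at E18.5 to 805 at 2 weeks.

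Between 2 weeks and adulthood the Lin28b list fell while antigen presentation genes rose, now within marrow. At 2 weeks 4847 genes differed from adults, 2135 higher and 2712 lower, with the same direction in each population for 86.5% and a difference over 2-fold in 1167 (500 higher, 667 lower). Igf2bp3 was 6.31 ± 0.17 higher at 2 weeks (2.6e-22), Lin28b 4.14 ± 0.39 (1.7e-09), Hmga2 2.13 ± 0.09, the actin bundler Fscn1 2.80 ± 0.18 and the matrix protein Postn 3.17 ± 0.30. The creatine carrier Slc16a12 fell by 5.86 ± 0.56, H2-Q6 by 4.92 ± 0.13, H2-Q7 by 4.54 ± 0.12 and the neural protein Npdc1 by 4.53 ± 0.32. Without the 3 libraries with the most Alb or Tpsb2 4766 genes differed, without the E18.5 libraries numbered 2 the count was 5453, and with the length and GC correction 5813. At an adjusted p under 0.01, 3084 genes differed. With limma-voom and a random block by the number in the titles 3211 did, and by the number in the deposited names 2491. MHC class I had 13 of 16 genes lower at 2 weeks and 0 higher (13 adjusted over the list alone; median −0.62, 3.7e-16), and class II 8 of 10 lower and 1 (H2-DMb2) higher (8 and 1 adjusted over the list alone; −1.39, 3.2e-08). Of the Lin28b list 6 of 10 were higher and 0 lower (8 adjusted over the list alone; 1.04, 2.1e-10). Imprinted genes moved less, with 4 of 18 higher and 1 lower (5 and 1 adjusted over the list alone; 0.19, 0.017; adjusted p = 0.34 with an estimated correlation).

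Interferon genes were also lower at 2 weeks than in adults. Of 36 genes 25 were lower and 0 higher (27 adjusted over the list alone), with a median of −0.38 (6.9e-11), among them the nucleic acid sensor Zbp1 (−1.80 ± 0.14) and the nuclease Isg20 (−0.80 ± 0.07), but Irf7 did not pass (−0.13, 0.40). Histone genes were higher at 2 weeks, 32 of 54 with 0 lower (37 adjusted over the list alone; median 0.66, 4.8e-12; adjusted p = 0.14 with an estimated correlation), as were 9 of 31 proliferation genes with 0 lower (12 adjusted over the list alone; 0.14, 4.1e-04; adjusted p = 0.26 with an estimated correlation). Cholesterol synthesis genes were lower, 13 of 17 with 0 higher (13 adjusted over the list alone; −0.54, 4.7e-07; adjusted p = 0.18 with an estimated correlation). Neutrophil genes had 7 of 12 lower and 0 higher (7 adjusted over the list alone; −2.42, 1.9e-05), and macrophage genes 11 of 14 lower and 0 higher (11 adjusted over the list alone; −3.35, 3.7e-09; adjusted p = 0.056 with an estimated correlation). Hepatocyte genes had 10 of 14 lower and 1 (Hnf4a) higher (12 and 1 adjusted over the list alone), with a median of −4.23 (0.013, and adjusted p = 0.67 with an estimated correlation). The median was −0.89 without the 3 libraries with the most Alb or Tpsb2. The macrophage lectin Fcna, −4.38 ± 0.50, stood at 36.6 ± 27 CPM in adult MPP2 and 0.310 to 0.427 in the groups of 2 weeks.

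**Figure D5:**
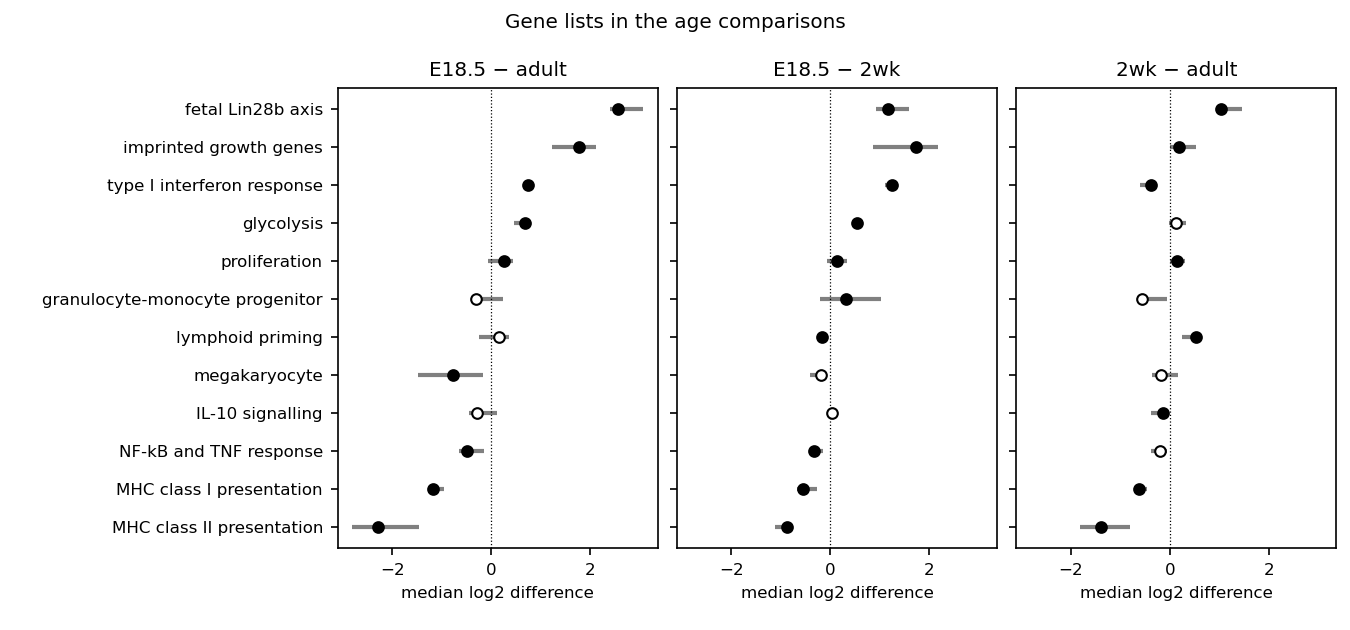
Points give the median log2 difference of a gene list in each age comparison, filled where the list test had an adjusted p under 0.05, and grey bars run from the lowest to the highest median of the 4 populations. Interferon genes lie at 0.75, 1.25 and −0.38 in the 3 comparisons, and MHC class II genes at −2.28, −0.88 and −1.39.

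The age difference was called as unequal between populations for 758 genes between E18.5 and adult, 120 between E18.5 and 2 weeks and 137 between 2 weeks and adult. Without adult MPP2 replicate 3 the last count was 235, and without the 3 libraries with the most Alb or Tpsb2 240; without the E18.5 libraries numbered 2 the middle one was 76. DESeq2 gave 1171, 286 and 374, and an adjusted p under 0.01 gave 401, 48 and 64. Of 30 divisions of the libraries, the real one included, 3 gave as many genes for the first count and 2 for the last. Chance is left open for each of these counts, as described below. The smallest adjusted p of the first test belonged, among genes of known name, to Dntt, which adds untemplated bases in lymphoid cells (ENSMUSG00000025014.13, chromosome 19, 41029275 to 41059525): 828 ± 42 CPM in adult MPP4 and 805 ± 210 at 2 weeks, but 1.77 ± 0.42 in E18.5 MPP4. Its difference between E18.5 and adult was −8.87 in MPP4, −5.09 in MPP3 and −0.11 in HSC, a range of 8.75 (3.0e-12). The monocarboxylate carrier Slc16a11 rose at each step in MPP4, with 1.05 ± 0.29, 22.2 ± 7.0 and 75.6 ± 16 CPM at the 3 ages, against 4.69 ± 0.82, 7.67 ± 1.8 and 2.94 ± 0.60 in HSC. Gfi1, a repressor that limits stem cell cycling, was higher at E18.5 in HSC (181 ± 35 against 19 ± 4.6 CPM) and MPP2 (47.3 ± 18 against 6.40 ± 2.1), with 81.5 ± 4.5 against 103 ± 17 in MPP4 (range 3.59, 5.3e-08). The actin regulator Cnn3 fell with age most in HSC and MPP2 (4.10 and 4.44) and least in MPP4 (1.85). Between 2 weeks and adult it belonged to the mucin Muc13 (chromosome 16, 33794037 to 33819934), whose rise to adulthood was largest in MPP4, from 21.2 ± 6.8 to 287 ± 13 CPM (range 2.68, 2.5e-06).

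MPP2 differed from HSC in 7428 genes averaged over the 3 ages (3616 higher, 3812 lower; over 2-fold 544 higher, 1805 lower), 96.8% in the same direction at each age. HSC signature genes were lower, 20 of 21 with 1 (Gata2) higher (the same adjusted over the list alone; median −1.78, 6.3e-16), among them Procr (−3.00) and Mecom (−2.15). All 31 proliferation genes were higher (31 adjusted over the list alone; 0.93, 3.8e-20). Erythroid genes had 13 of 21 higher and 0 lower (14 adjusted over the list alone; 1.36, 3.2e-05; adjusted p = 0.23 with an estimated correlation), with the erythroid factors Gata1 (2.22) and Klf1 (2.80). The erythroid median was 0.93 without the 3 libraries with the most Alb or Tpsb2. In adult MPP2 replicate 3, which holds liver mRNA, the globin gene Hbb-bs stood at 108 CPM, against 3.14 and 6.38 in its sister libraries. Mast cell and basophil genes had 6 of 11 higher and 0 lower (6 adjusted over the list alone), with a median of 1.17 (0.0040, and adjusted p = 0.37 with an estimated correlation). Of the 54 histone genes 39 were higher than in HSC and 1 lower (40 and 1 adjusted over the list alone), with a median of 1.03 (4.4e-11, and adjusted p = 0.16 with an estimated correlation). The largest increases included the G protein Gna14 (5.98 ± 0.18) and the interleukin-33 receptor Il1rl1 (6.19). Imprinted genes had 13 of 18 lower and 0 higher (13 adjusted over the list alone; −1.42, 9.8e-07), and Hox genes 12 of 16 lower and 1 higher (12 and 1 adjusted over the list alone; −1.18, 3.0e-05).

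MPP3 differed from HSC in 8167 genes (4019 higher, 4148 lower), 93.9% in the same direction at each age, and over 2-fold in 839 higher and 2043 lower. Granulocyte-monocyte genes rose by a median of 4.30, 18 of 21 higher and 1 (Gstm1) lower (18 and 1 adjusted over the list alone; 4.9e-16). The granule proteases Elane (9.11 ± 0.67) and Ctsg (9.09) and the myeloid factor Cebpa (4.81) were among them, and Mpo rose by 7.65 ± 0.25 to 4830 to 9890 CPM. Lists of other cell types rose beside them: mast cell and basophil genes by a median of 5.77 (8 of 11 higher, 1 lower, the same adjusted over the list alone, adjusted p = 1.6e-04, and adjusted p = 0.22 with an estimated correlation), and T and NK cell genes by 4.13 (8 of 11 higher, 1 lower, the same adjusted over the list alone, adjusted p = 2.9e-06). B cell genes rose by 4.0 (11 of 13 higher, 0 lower, the same adjusted over the list alone, adjusted p = 3.0e-05, and adjusted p = 0.19 with an estimated correlation) and neutrophil genes by 2.60 (7 of 12 higher, 1 lower, the same adjusted over the list alone, adjusted p = 0.0014, and adjusted p = 0.10 with an estimated correlation). All 21 HSC signature genes were lower (21 adjusted over the list alone; −2.35, 8.9e-21), and 12 of 17 megakaryocyte genes were, with 1 (Selp) higher (12 and 1 adjusted over the list alone; −1.25, 4.7e-07). Histone genes had 41 of 54 higher and 2 lower (44 and 2 adjusted over the list alone), with a median of 0.93 (1.6e-08, and adjusted p = 0.23 with an estimated correlation). The caveolar coat protein Cavin2 fell by 7.40 ± 0.23, and the clotting factor Vwf was also lower (−5.66).

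MPP4 differed from HSC in 8395 genes (4101 higher, 4294 lower), 94.5% in the same direction at each age, and over 2-fold in 869 higher and 2345 lower. Lymphoid genes had 13 of 16 higher and 0 lower (14 and 1 adjusted over the list alone), with a median of 2.56 (1.3e-11): Dntt rose by 7.10 ± 0.22, by 10.03 at 2 weeks and 10.02 in adults but 1.27 at E18.5, and the interleukin-7 receptor Il7r by 7.84. The sort-gate receptor Flt3 rose by 3.40 ± 0.13, the chemokine receptor Ccr9 by 8.08 and the lymphoid inhibitor Btla by 8.69. All 17 megakaryocyte genes were lower (17 adjusted over the list alone; −3.33, 4.9e-16), as were all 21 HSC signature genes (21 adjusted over the list alone; −2.58, 2.0e-21), and Gata1 fell by 5.01. B cell genes had 7 of 13 higher and 0 lower (7 adjusted over the list alone), with a median of 2.02 (0.0053, and adjusted p = 0.42 with an estimated correlation). T and NK cell genes had 5 of 11 higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 2.16 (0.0071, and adjusted p = 0.18 with an estimated correlation). Histone genes had 39 of 54 higher and 0 lower (39 adjusted over the list alone), with a median of 1.02 (1.2e-08, and adjusted p = 0.23 with an estimated correlation). Granulocyte-monocyte genes had 15 of 21 higher and 1 (Gstm1) lower (15 and 1 adjusted over the list alone; 2.32, 5.8e-09).

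The receptor for interleukin-10 was read in each population. Its ligand-binding chain Il10ra (ENSMUSG00000032089.16, chromosome 9, 45253837 to 45269149) was 1.47 ± 0.24 higher at E18.5 than in adults (9.3e-06) and 1.46 ± 0.24 higher than at 2 weeks (2.1e-05); averaged over the populations 2 weeks and adult did not differ past the threshold (0.01, 1.0), with 0.92 in HSC and −0.71 in MPP4. The difference from adults depended on the population (range 3.52, 0.0072): 16.7 ± 6.9 against 1.51 ± 1.1 CPM in MPP2, 13.9 ± 6.7 against 4.72 ± 1.7 in HSC, 32.8 ± 22 against 17.5 ± 1.8 in MPP3 and 46.9 ± 13 against 48.8 ± 5.3 in MPP4. In each population E18.5 replicate 1 had the highest value of the 3, with 21.3 CPM in HSC, 24.4 in MPP2, 58.2 in MPP3 and 61 in MPP4. Those of HSC, MPP2 and MPP3 also held mast cell mRNA and the most C1qa of the 3. The shared chain Il10rb fell by 0.41 ± 0.06 at E18.5 relative to adults (4.4e-06). Of 14 interleukin-10 signalling genes 4 (Socs1, Il10ra, Nfil3, Il4ra) were higher at E18.5 than in adults and 6 lower (4 and 6 adjusted over the list alone), and the list did not pass (0.29). Between 2 weeks and adult 6 were lower and 0 higher (6 adjusted over the list alone; median −0.14, 0.043; adjusted p = 0.59 with an estimated correlation), among them the feedback inhibitor Socs3 (−1.97 ± 0.17).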

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

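The tests on liver genes, on mast cell genes and on macrophage RNA were written only after the values were seen, as were the fits without 3 or 4 libraries and the length and GC correction. The other tests were written before.

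Adult MPP2 replicate 3 holds liver mRNA that its 2 sister libraries lack. The other libraries of its deposited number had Alb at 10.8 CPM (adult MPP3 replicate 3), 0.70 (adult HSC replicate 3) and 0.165 (adult MPP4 replicate 3). In adult MPP2 replicate 3, 12 of 14 hepatocyte genes were over 4-fold above both sisters. The list without Trf reached at most 4.8% of its level there in a sister library. These 2 values restate how the library was found, so they neither support nor exclude an explanation. Its Alb level was 160 times that of the E18.5 library with the most, so carry-over from the E18.5 libraries of this series does not account for it. Those libraries hold sorted cells with Alb at 1.32 CPM or less. The comparison therefore does not address RNA of unsorted liver, fetal or adult. No biological explanation was tested.

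The interferon response list was higher at E18.5 than at both other ages. Its lower median difference was 0.75 after the length and GC correction and 0.78 without the E18.5 libraries numbered 2, so neither accounts for it. The summed macrophage list at E18.5 was at most 0.47 of that of adults in any population, or 0.61 without Cd163. RNA of mature macrophages therefore does not account for the difference from adults. Against 2 weeks, the E18.5 library of each population with the least macrophage list CPM without Cd163 (18.5 to 43.6) lay below each 2-week library. Its interferon median stood at least 0.99 above the 2-week mean. In MPP3 and MPP4 the summed C1q genes of that library (0.642 and 1.05 CPM) were also below the 2-week mean (1.9 and 2.85). Macrophage RNA thus does not account for the difference from 2 weeks in those libraries. In HSC and MPP2 the C1q sum of that library (4.07 and 2.88 CPM) was above the 2-week mean (3.49 and 2.33). In E18.5 HSC replicate 3 both sums (47.6 and 2.42 CPM) lay below 2 weeks (58 and 3.49), with an interferon median of 1.52. The C1q sum of E18.5 HSC replicate 1 was 11.1 CPM. The question stays open for HSC and MPP2 as groups. Fetal liver against marrow and fetal against later age remain as explanations that the design cannot separate. A difference in sort day or cell handling between ages was not tested.

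E18.5 MPP3 replicate 1 holds mast cell mRNA, and less of it stands in E18.5 HSC and MPP2 replicates 1 (Tpsb2 33.5 and 37.6 CPM) and in E18.5 MPP3 replicate 2 (42.8). Of 11 mast cell genes 8 were over 4-fold above both sister libraries, and Tpsb2 and Cma1 together reached at most 0.8% of their level in a sister library. Both values restate how the library was found, so its source stays open. No biological explanation was tested.

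Among the named genes reported here, 103 age or population differences were themselves unequal between populations or ages by an interaction test, given here as the distance in log2 units between the highest and the lowest effect. Distances of genes near 0 CPM in a group depend on the prior count. Leaving out 1 library ended 27 of these calls. Between populations they were Afp, Gp5, Id3, Klf1 and S100a8 for E18.5 minus adult, Asns, Cpne2, Dlk1, Ifitm1, Igf2bp2 and Klf1 for E18.5 minus 2 weeks, and Aldoc, Fscn1 and Ndn for 2 weeks minus adult. Between ages they were Ifitm1, Pdgfc, Pdgfrb and Tmem173 for MPP2, Flt3, Ifi44 and Vwf for MPP3, and Aldoc, Flt3, Gp5, Nfil3, Pdgfrb and Pf4 for MPP4. The distance of Afp was 0.73 (adjusted p = 0.66) without adult MPP2 replicate 3, the library with liver mRNA. Those of Klf1 without E18.5 MPP3 replicate 1 were 1.98 for E18.5 minus adult and 2.79 both for E18.5 minus 2 weeks and for MPP3. That of Evc2 for MPP4 was 7.47 without 2-week MPP4 replicate 2. Without the 3 libraries with the most Alb or Tpsb2, 6 calls ended: Afp, Klf1 and S100a8 for E18.5 minus adult, Asns and Klf1 for E18.5 minus 2 weeks, and Klf1 for MPP3. For E18.5 minus adult between populations, 31 genes were unequal: Dntt 8.75, Elane 6.93, Slc16a11 6.84, Aldh1a1 5.57, S100a8 5.25, Clec10a 4.56, Bgn 3.96, Klf1 3.72, Gfi1 3.59, Afp 3.59, Il10ra 3.52, Pf4 3.36, Id3 2.99, Procr 2.93, Fcgr2b 2.87, H2-Q6 2.71, Gata1 2.65, Pcdh7 2.64, Cnn3 2.59, H2-Q7 2.53, Mecom 2.20, Pdgfrb 2.08, Pdzk1ip1 2.07, H2-Ab1 1.98, Flt3 1.91, Ndn 1.89, Gp5 1.82, Nkg7 1.73, Ly6a 1.39, Asns 1.33 and Itgb2 1.32. For E18.5 minus 2 weeks there were 16: Dntt 8.76, Elane 8.74, Rasal1 8.02, Klf1 4.56, Slc16a11 3.69, Rgs1 3.61, Cxcr2 2.81, Cnn3 2.63, Fcgr2b 2.35, Gata1 2.20, Igf2bp2 2.01, Dlk1 1.98, Lck 1.76, Cpne2 1.69, Asns 1.24 and Ifitm1 1.12. For 2 weeks minus adult there were 13: Clec10a 3.15, Slc16a11 3.15, Gfi1 3.12, Muc13 2.68, Fscn1 2.42, H2-Ab1 2.24, H2-Q6 2.22, Procr 1.98, Ctsf 1.90, H2-Q7 1.76, Ifitm1 1.72, Ndn 1.44 and Aldoc 1.30.

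Between ages, the difference of MPP2 from HSC was unequal for 5 named genes: Pdgfc 4.95, Pdgfrb 2.08, Ndn 1.89, Ifitm1 1.12 and Tmem173 1.05. That of MPP3 was unequal for 20: Blnk 7.99, Evc2 7.58, Dntt 4.97, Klf1 4.56, Pf4 3.11, Fcgr2b 2.87, Gata1 2.65, Mecom 2.20, Cxcr2 2.09, H2-Q7 2.08, Igf2bp2 2.07, Vwf 1.99, H2-Q6 1.90, Cebpa 1.86, Procr 1.79, Nkg7 1.73, Ifi44 1.61, Ndn 1.48, Flt3 1.45 and Ctnnal1 1.39. That of MPP4 was unequal for 18: Dntt 8.76, Rasal1 8.02, Evc2 4.72, Pf4 2.93, Cxcr2 2.81, Igf2bp2 2.76, H2-Q6 2.71, H2-Q7 2.53, Gata1 2.48, Fcgr2b 2.19, Nfil3 2.00, Pdgfrb 1.98, Gp5 1.82, Pdzk1ip1 1.80, Procr 1.73, Flt3 1.33, Lck 1.26 and Aldoc 1.16.

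Other divisions of the same libraries tested whether chance could give as many genes. In 30 divisions each, only 1 division, the real one, gave as many genes for the averaged differences. Between ages these were E18.5 minus adult 6701 (highest other 2827), E18.5 minus 2 weeks 4566 (14) and 2 weeks minus adult 4847 (2). Between populations they were MPP2 minus HSC 7428 (5), MPP3 minus HSC 8167 (1558) and MPP4 minus HSC 8395 (211). The other divisions mix groups with a large difference, which widens the spread within them, so these counts alone do not exclude chance.

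For differences between differences, no other division gave as many genes in 2 counts, population dependence of E18.5 minus 2 weeks (120, 1 of 30, highest other 18) and age dependence of MPP3 minus HSC (331, 1 of 30, highest other 93). Other divisions did in 4 counts: population dependence of E18.5 minus adult (758; 3 of 30, highest other 2809) and of 2 weeks minus adult (137; 2 of 30, highest other 312), and age dependence of MPP2 minus HSC (72; 3 of 30, highest other 3463) and of MPP4 minus HSC (377; 4 of 30, highest other 4297). Counts several times the real one point to a structure of the samples. In each division with as many genes, at least 1 population or age kept its groups whole or exchanged them whole while another was mixed or turned, which carries the large age or population difference into this test. Divisions that mix groups with a large difference also widen the spread within them. They are therefore no measure of chance alone, and the question stays open for all 6 counts.

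Within populations, 3 against 3 libraries give 10 divisions, too few for a share under 0.05; the real one alone (1 of 10) gave as many in each. For E18.5 minus adult the real values and highest others are 2128 and 0 in HSC, 2272 and 584 in MPP2, 3412 and 3 in MPP3, and 2763 and 0 in MPP4. For E18.5 minus 2 weeks they are 911 and 2, 855 and 1, 1322 and 2, and 1084 and 1. For 2 weeks minus adult they are 708 and 0, 1164 and 1, 1735 and 0, and 1303 and 0.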

How the results depend on the processing

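The fits without the 3 libraries with the most Alb or Tpsb2 mRNA, without the 4 E18.5 libraries numbered 2 and with the length and GC correction were chosen only after the data were seen. Among the counts of genes and the count of list calls, 608 alternative values stayed within 1.5 times the main value, 38 were higher and 62 lower. The balance of higher and lower genes turned for E18.5 minus adult with size factors of the DESeq2 kind (3391 higher, 3339 lower), DESeq2 (3572, 3495), the length and GC correction (4037, 3629) and without adult HSC replicate 1 (3302, 3285), MPP2 replicate 3 (3252, 3217), MPP3 replicate 3 (3221, 3208) or MPP4 replicate 1 (3421, 3381). It turned for E18.5 minus 2 weeks with upper-quartile factors (2260 higher, 2296 lower). The length and GC correction turned it for MPP2, MPP3 and MPP4 minus HSC (4560, 4982 and 5128 higher, 3857, 4089 and 4276 lower). It turned for MPP2 also without adult HSC replicate 1 (3693, 3692), and for MPP3 at an adjusted p under 0.01 (3071, 3063) and without 2-week HSC replicates 2 (3916, 3904) or 3 (3916, 3882), adult HSC replicate 1 (4096, 3972), adult MPP3 replicate 1 (3933, 3877), E18.5 HSC replicate 2 (4142, 4085) or E18.5 MPP3 replicate 3 (4048, 4040). With upper-quartile factors MPP2, MPP3 and MPP4 minus HSC had 2842, 3436 and 3178 genes higher and 4456, 4660 and 4895 lower. Of the named gene values 19565 kept their direction and side of the threshold, 89 passed newly, 177 were lost and 52 changed sign without a call. Of the list values 7872 were kept, 79 passed newly, 112 were lost and 127 moved. For the changes below the cause was not tested, except that fewer libraries or a stricter threshold call fewer genes by construction.

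At an adjusted p under 0.01, E18.5 minus 2 weeks fell to 2986 and 2 weeks minus adult to 3084. In HSC, MPP2, MPP3 and MPP4, E18.5 minus adult fell to 1278, 1370, 1881 and 1698, E18.5 minus 2 weeks to 404, 445, 586 and 542, and 2 weeks minus adult to 342, 555, 728 and 675. Genes whose age difference depends on population fell to 401, 48 and 64, and whose population difference depends on age to 21, 168 and 211. With an estimated correlation, list calls fell from 101 to 32.

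DESeq2 gave 1372 genes for E18.5 minus 2 weeks in HSC and 1298 in MPP2, 1171, 286 and 374 for population dependence, and 191, 555 and 600 for age dependence. Limma-voom gave 1077 for 2 weeks minus adult in HSC. The length and GC correction gave 1466, 1414 and 1997 for E18.5 minus 2 weeks in HSC, MPP2 and MPP3, 1088, 1831 and 2093 for 2 weeks minus adult in HSC, MPP2 and MPP4, and 114 for age dependence of MPP2. Without the 3 libraries with the most Alb or Tpsb2, population dependence of 2 weeks minus adult gave 240, and without the E18.5 libraries numbered 2 that of E18.5 minus 2 weeks gave 76. With only the libraries compared, E18.5 minus adult gave 1024 in MPP2 and 1027 in MPP3, E18.5 minus 2 weeks 193 in MPP3 and 2163 in MPP4, and 2 weeks minus adult 1186 in HSC and 542 in MPP2.

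Libraries share numbers within an age, and a block on them was tried although the labels do not pair them. The main fit counts libraries of a shared number as independent, and no list test was run with a block. Residuals of libraries with the same title number correlated above 0.1 in 10 of 18 pairs at E18.5, 0 of 18 at 2 weeks and 8 of 18 in adults, and each library correlated best with its own number in 12, 12 and 8 of 12. The number in the deposited names differs from the title in 16 of 36 libraries; with it, 12 of 14 adult pairs were above 0.1 and 12 of 12 libraries fit best with their own. A random block by title number gave 2974 for E18.5 minus 2 weeks, 3211 for 2 weeks minus adult, 1081 for 2 weeks minus adult in HSC, 1269, 207 and 366 for population dependence, and 139, 574 and 607 for age dependence. A random block by the deposited number gave 4325, 2110 and 2491 for the 3 averaged age differences, 1155 for 2 weeks minus adult in HSC, 1519, 347 and 527, and 176, 793 and 742. The consensus correlation within these blocks was 0.327. Of the named gene values 538 then kept their direction and side of the threshold, 31 were lost, 4 passed newly and 2 changed sign without a call. A block within age gave 195 and 290 for population dependence from E18.5 and adult to 2 weeks, and 137 and 511 for age dependence of MPP2 and MPP3.

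Leaving out each library in turn moved E18.5 minus 2 weeks to 499 to 642 in HSC, 498 to 715 in MPP2, 688 to 1347 in MPP3 and 594 to 899 in MPP4. By over 1.5 times moved it: in HSC 2-week replicates 1 (587), 2 (499) and 3 (530) and E18.5 replicates 1 (564) and 3 (564); in MPP2 2-week replicates 2 (498) and 3 (538); in MPP3 2-week replicates 2 (688) and 3 (815); in MPP4 2-week replicates 2 (594) and 3 (686) and E18.5 replicates 1 (711) and 3 (714). For 2 weeks minus adult the ranges were 357 to 506, 658 to 1560, 951 to 1242 and 848 to 1113. There the libraries were, in HSC, 2-week replicate 1 (395) and adult replicates 1 (357) and 3 (466); in MPP2 2-week replicates 1 (658) and 3 (720) and adult replicate 2 (714); in MPP3 2-week replicates 1 (1076), 2 (955) and 3 (1037) and adult replicates 1 (951) and 3 (1137); in MPP4 2-week replicates 1 (848) and 3 (857) and adult replicate 2 (849). Population dependence of 2 weeks minus adult ranged from 106 to 235, the highest without adult MPP2 replicate 3. Age dependence of MPP2 ranged from 33 to 106, with 42 without adult HSC replicate 2 and 33, 41 and 42 without E18.5 HSC replicates 1, 2 and 3.

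At 32.0 to 51.3 M counts per library and 3 libraries per group, differences under 2-fold within 1 population are the ones most often missed: in simulated E18.5 minus adult data of MPP4, 22.4% of 1.5-fold changes were recovered.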

Other observations

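The comparison of exon length with the deposited numbers was chosen only after the data were seen, as were Cd163 beside C1qa and the genes outside the naming rule. Single adhesion genes differed with age, while the homing list as a whole did not. Selp, the P-selectin of platelets and endothelium, stood at 93.6 ± 4.6 CPM in adult MPP3, 14.1 ± 2.0 at 2 weeks and 32.8 ± 2.4 at E18.5; it fell by 2.78 ± 0.14 at 2 weeks relative to adults (adjusted p = 4.4e-15). The homing list had 4 of 16 genes higher at E18.5 than in adults (Itgb2, S1pr1, Robo4, Itga4) and 4 lower (Vcam1, Cxcr4, Itgam, Itga6), the same adjusted over the list alone, and did not pass (0.86). Of 14 genes of the unfolded protein response 9 were lower at E18.5 than in adults and 1 (Asns) higher (9 and 2 adjusted over the list alone; median −0.32, 0.056).

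Ribosomal protein genes had 22 of 86 higher at E18.5 than in adults and 1 (Rpl21) lower (13 and 1 adjusted over the list alone), with a median of 0.18 (4.2e-04; adjusted p = 0.82 with an estimated correlation), which was −0.03 without the E18.5 libraries numbered 2. In MPP3 they had 79 of 86 higher than in HSC and 1 lower (81 and 1 adjusted over the list alone; 0.51, 1.3e-13; adjusted p = 0.47 with an estimated correlation). Hox genes of the A and B clusters were lower in MPP3 than in HSC, 13 of 16 with 0 higher (13 adjusted over the list alone; −1.53, 1.0e-06).

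Cd163 did not follow other macrophage genes. It rose from 0.513 ± 0.45 CPM at E18.5 over 7.34 ± 0.99 at 2 weeks to 17.8 ± 1.9 in adult HSC, and to 29.4 ± 5.1 in adult MPP4, while C1qa stood at 1.36, 1.16 and 6.21 CPM in HSC at the 3 ages and was highest in adult MPP2 (27.8 ± 19).

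Xist, expressed in female cells, was 1.30 ± 0.23 lower at E18.5 than at 2 weeks (6.2e-05) and 0.81 ± 0.22 higher at 2 weeks than in adults (0.0073), and the male gene Ddx3y did not differ (−0.04 and −0.20).

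The correlation of a gene's deviation from its group mean with its exon length, over 9181 genes, differed between some of the numbers in the deposited names. At E18.5 it was 0.02 to 0.47 in number 1, −0.62 to −0.29 in number 2 and 0.32 to 0.53 in number 3. In adults it was −0.30 to −0.16, −0.47 to −0.02, 0.05 to 0.20 and 0.30 to 0.54 in numbers 1 to 4. At 2 weeks the numbers overlapped, with −0.17 to 0.01 in number 1, −0.01 to 0.35 in number 3 and −0.31 to 0.09 in number 4.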
